A study of Homo sapiens with 12 samples.

How the data were processed

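RNA was sequenced from A549 cells, a human lung adenocarcinoma line, and from a derivative in which the link between the microRNA miR-22 and its target SNAI1 was edited. Each line was kept untreated or given TGFβ, an inducer of epithelial-mesenchymal transition (EMT), at 10 ng/mL and was sampled at day 5. The 4 groups held 3 libraries each, which the labels call biological repeats. P-values measure the spread between these repeats. A single edited derivative was sequenced, so the edit and the derivation of the line cannot be separated.

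The deposited values are a signal of normalized counts per gene, made by the authors from reads. Per the submitters' processing notes, HISAT2, StringTie, featureCounts and DESeq2 were used with the build GRCh38.p14. Their versions, roles and order, and the annotation release, are not given in the sources used here. In each library the values were whole multiples of a constant step. Dividing by that step gave whole reads for 100% of values within a tolerance of 0.01 (largest deviation 0.000336), and the inverse of each step equalled the median-of-ratios size factor computed from those reads. In replicate 1 of untreated wild type the step lay close to 1 (0.996884, largest deviation 5.4e-05). Its values were not whole numbers (CDH2 at 9.96884), so rounding to whole numbers would not give this pattern. The recovered reads ran from 84210775 to 111141708 per library. The table held 58830 entries, of which 28 carried gene names turned into dates; these stayed in the tests and are not named. Whether the counting used strand is not given in the sources used here. Values of overlapping and antisense genes, and of families of similar genes such as histones and the LCE3 and IGFL families, are therefore uncertain.

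Genes with a value of at least 10 in at least 3 of the 12 libraries were tested, which left 20456. Values were analysed as log2(value + 1) with limma 3.58.1 (trend) in R 4.3.3, in a single fit of the 4 group means. From it came 5 comparisons, each two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. They were TGFβ against untreated in each line, the edited line against wild type in each condition, and the difference between the lines in their TGFβ response (the interaction). Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Values after ± are standard errors for log2 fold changes and SD for group means, with n = 3 libraries per group.

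The groups, comparisons, main test, gene lists and rule for named genes were fixed before the data were examined. Of 33 gene lists, the 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The rule named SNAI1, MIR22HG and 8 marker genes with any result. It added the top 8 genes each way for TGFβ in wild type and for the untreated edited line and the top 5 each way elsewhere, by log2 fold change among called genes with a mean of at least 100 and no overlap between the libraries compared (overlap was allowed for the interaction). It also took up to 4 called members of each list described. Some genes that the rule names are not reported here.

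The test was checked on simulated counts with 200 changed genes per comparison. For the untreated edited line, over 18915 simulated genes, it recovered 64.2% of 1.5-fold, 76.1% of 2-fold and 95.5% of 4-fold changes, and 6.55% of its calls were unchanged genes. For the interaction, over 18912 genes, it recovered 32.8% of 1.5-fold, 73.1% of 2-fold and 84.8% of 4-fold changes, and 4.51% of its calls were unchanged genes. The 200 changed genes are fewer than each real comparison called, so these rates need not hold for the real data. The list test, simulated for the untreated edited line over 20456 genes, recovered 5 of 5 moved lists and called 0 of the others. Its simulated genes were drawn independently, so it does not check false calls of lists with correlated members. Ribosomal protein genes, for example, had an estimated correlation of 0.970.

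Alternatives covered the pseudocount, the filter, the scaling (equal totals, quantile normalization, TMM), robust variance estimates, a replicate block, fits of the compared groups alone, and leaving out each library. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test) called 12669 genes for TGFβ in wild type, 6529 for the untreated edited line, 12803 for TGFβ in the edited line, 2564 for the edited line with TGFβ and 3404 for the interaction. DESeq2 1.42.0 was also run on them. Removal of transcript length or GC trends, and exclusion of 2 libraries or of chromosomes 8 and 9, were chosen after the data were seen. Gene positions, transcript lengths and GC content came from GENCODE 29 on GRCh38, which gave a length for 80.8% of tested genes.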

Results

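Gene expression was measured by RNA-seq in 12 libraries of A549 cells, 3 for each combination of genotype (wild type or the edited derivative, called here the edited line) and treatment (untreated or TGFβ). Recovered reads ran from 84210775 to 111141708 per library. Principal component 1 held 70.5% of the variance and separated TGFβ-treated from untreated libraries. Component 2 held 7.89% and separated the genotypes.

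**Figure D1:**
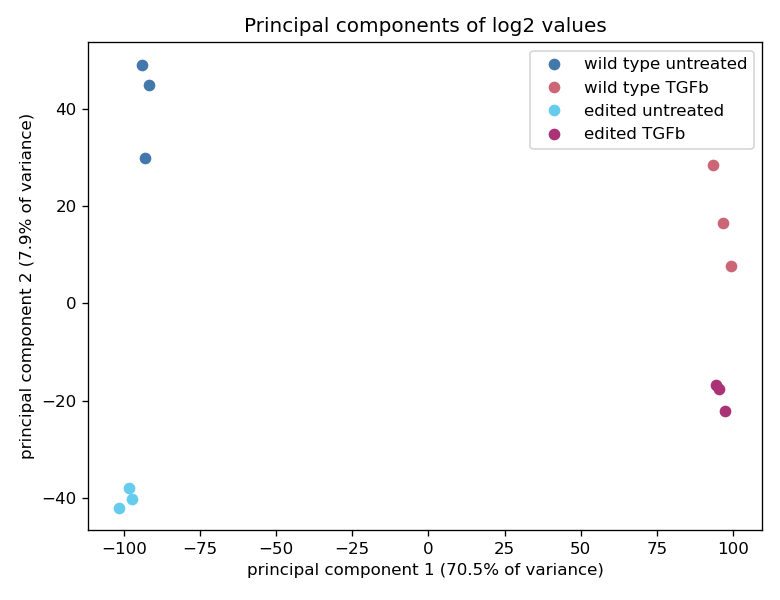
Principal components 1 and 2 of the log2 values; each point is a library, coloured by group. Treated and untreated libraries lie apart on component 1 (70.5% of the variance) and the genotypes lie apart on component 2 (7.89%).

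The edited link joins miR-22 to SNAI1, so SNAI1 and MIR22HG, the host transcript of miR-22, are given before all other genes. SNAI1 (ENSG00000124216.3, GRCh38 chromosome 20, 49982999 to 49988886) encodes a repressor of epithelial genes. Its normalized count was 496 ± 88.6 in untreated wild type and 481 ± 43.4 in the untreated edited line, a log2 fold change of -0.03 ± 0.13 that did not pass the test (adjusted p = 0.884) and was above 0 without replicate 3 of untreated wild type (0.0853) or replicate 3 of the untreated edited line (0.05). With TGFβ, SNAI1 rose to 875 ± 97.2 in wild type and to 1313 ± 96.5 in the edited line, and it was higher in the edited line (log2 fold change 0.59 ± 0.13, adjusted p = 0.00685). The response was larger in the edited line by 0.62 ± 0.18 on the log2 scale (adjusted p = 0.0279). That call was lost without replicate 1 or 3 of untreated wild type (0.59 and 0.50), replicate 2 of treated wild type (0.64), replicate 3 of the untreated edited line (0.54), or replicate 1 or 3 of the treated edited line (0.57 and 0.61).

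MIR22HG (ENSG00000186594.14, GRCh38 chromosome 17, 1711493 to 1717174), a long non-coding RNA gene, rose with TGFβ from 2532 ± 266 to 5073 ± 96.7 in wild type and from 2768 ± 225 to 4607 ± 397 in the edited line. No difference between the lines was detected for MIR22HG without TGFβ (log2 fold change 0.13 ± 0.08, adjusted p = 0.262) or with it (-0.14 ± 0.08, adjusted p = 0.313). Its interaction was -0.27 ± 0.12 (adjusted p = 0.132) and passed without replicate 2 of untreated wild type (-0.36). Mature miR-22 was not analysed here. An edit of a target site need not change SNAI1 reads, so these values do not check the genotype labels.

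**Figure D2:**
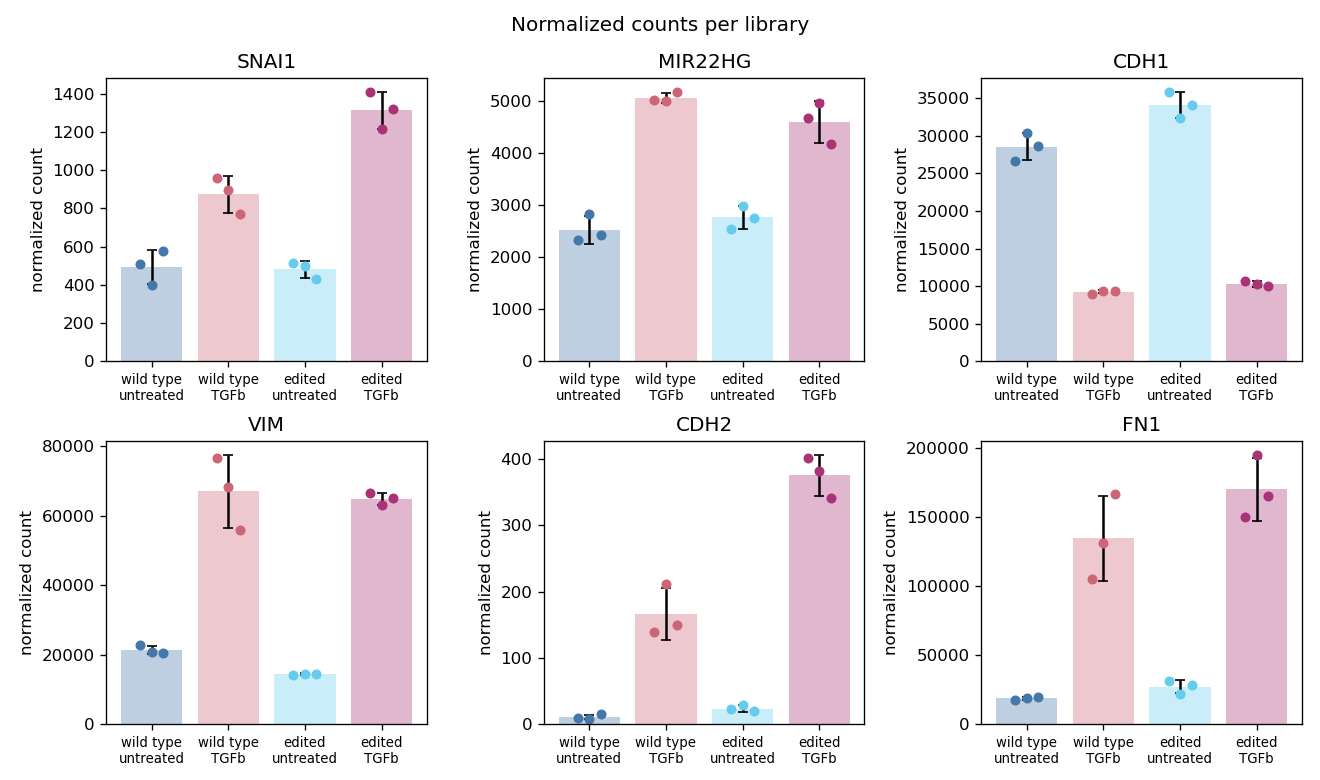
Normalized counts of SNAI1, MIR22HG, CDH1, VIM, CDH2 and FN1; points are libraries, bars are group means and whiskers are SD (n = 3). SNAI1 averaged 1313 in the treated edited line and 875 in treated wild type, and 481 and 496 without TGFβ.

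The first comparison asked how wild type cells responded to TGFβ. The matrix genes MMP2, COL22A1, SPOCK1 and COL5A1 rose from 1.69 ± 2.06, 6.19 ± 5.40, 24.7 ± 8.92 and 77.6 ± 12.9 to 4012 ± 319.7, 9606 ± 691, 27031 ± 2486 and 49032 ± 5879. LCE3D and WNT7A were listed at 0 in every untreated wild type library and averaged 2300.1 ± 489.8 and 616 ± 22.6 with TGFβ. The secreted mucins MUC5B and MUC5AC (-7.90 ± 0.13 and -6.44 ± 0.28), the bile acid transporter subunit SLC51B (-6.66 ± 0.15) and the gap junction gene GJB1 (-7.14 ± 0.73) fell. Among the markers, CDH1 (E-cadherin, -1.63 ± 0.06) and EPCAM (-0.86 ± 0.09) fell. VIM (vimentin, 1.63 ± 0.09), FN1 (fibronectin, 2.81 ± 0.14), CDH2 (N-cadherin, 3.81 ± 0.26), SNAI2 (3.55 ± 0.37) and ZEB1 (0.40 ± 0.10) rose.

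Of 24 mesenchymal and cytoskeletal genes, 21 rose and 0 fell in wild type, including the integrin ITGA11 (8.08 ± 0.22) and SPARC (7.72 ± 0.30). Matrix proteases and inhibitors rose in 15 of 18 members, collagens and crosslinkers in 17 of 22, with COL1A1 at 7.98 ± 0.09, and direct SMAD response genes in 19 of 24, with PDGFB at 6.66 ± 0.14. These lists passed camera (adjusted p = 1.27e-12, 4.97e-07, 7.65e-10 and 9.13e-11) and did so with an estimated correlation (adjusted p = 0.000989, 0.00426, 0.00369 and 0.0137). EMT transcription factors rose in 12 of 15 members, with SOX4 at 1.84 ± 0.06 (camera adjusted p = 0.00481; adjusted p = 0.0518 with an estimated correlation). The p53 targets rose in 13 of 20 (14 adjusted over the list alone) and fell in 4 (camera adjusted p = 0.0370; adjusted p = 0.384 with an estimated correlation). For the other called lists of this comparison, counts adjusted over the list alone were equal to those given.

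Epithelial junction and keratin genes moved both ways, with 20 of 31 lower, including TJP3 (-4.41 ± 0.12) and CLDN7 (-2.77 ± 0.23), and 5 higher, including PRSS8 (5.11 ± 0.69) and CLDN4 (3.06 ± 0.14) (camera adjusted p = 0.0126; adjusted p = 0.291 with an estimated correlation). NRF2 targets, genes of the oxidative stress response, fell in 23 of 25 members, led by ALDH3A1 (-3.87 ± 0.11), while HMOX1 rose (2.29 ± 0.09) (camera adjusted p = 2.25e-07; adjusted p = 0.255 with an estimated correlation). ER stress and amino acid response genes fell in 14 of 21 and rose in 4, led by TRIB3 (-4.05 ± 0.08) and CHAC1 (-2.89 ± 0.13) (camera adjusted p = 0.000154; adjusted p = 0.359 with an estimated correlation). Complement and coagulation genes fell in 12 of 20 and rose in 5, with C5 at -3.33 ± 0.09 and the fibrinogen gene FGA at -3.27 ± 0.07 (camera adjusted p = 0.00801; adjusted p = 0.395 with an estimated correlation). Mitochondrially encoded mRNAs rose in 11 of 13, with MT-ATP8 at 0.85 ± 0.09 (camera adjusted p = 0.00801, and adjusted p = 0.678 with an estimated correlation). Mitochondrial reads made up 2.54% to 2.83% of untreated and 2.73% to 3.79% of treated wild type libraries, ranges that overlap.

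Fibroblast markers, listed as another cell type, rose in 5 of 6 members, with PDGFRA at 4.60 ± 0.32 (camera adjusted p = 0.0384; adjusted p = 0.195 with an estimated correlation). Their summed normalized count was 166 to 207 in untreated and 1247 to 1462 in treated wild type libraries. The camera call ended without replicate 1 or replicate 3 of treated wild type (list medians 2.64 and 2.61). Endothelial and leukocyte markers were not called (camera adjusted p = 0.582 and 0.918), with summed counts of 927 to 1109 and 203 to 278 in untreated and 2237 to 2762 and 275 to 372 in treated wild type libraries. In total, 6297 genes were higher and 6327 lower with TGFβ in wild type, of which 3090 and 2015 changed at least 2-fold.

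The second comparison asked how the edited line differed from wild type without TGFβ. The largest increases among named genes were in SLITRK6 (8.20 ± 7.42 to 291 ± 41.9), DCLK1 (29.4 ± 11 to 485 ± 24.9) and CRISP3 (84.3 ± 14.2 to 959.9 ± 21.8). The adhesion gene CHL1 (3.17 ± 0.25), PAPPA2 (3.14 ± 0.21) and SEMA5A (2.95 ± 0.25) were also higher. The chemokine CCL20 was lower (5081 ± 1139 against 1239.9 ± 110.4 in the edited line), as were OLR1, a receptor for oxidized lipoprotein (-2.32 ± 0.21), and the glucuronosyltransferase UGT1A7 (-1.93 ± 0.13). CDH1 was higher (0.26 ± 0.06) and VIM lower (-0.57 ± 0.09), while CDH2 (1.06 ± 0.26) and FN1 (0.52 ± 0.14) were higher. The FN1 call was lost without replicate 1 of the untreated edited line (0.42). EPCAM was at -0.24 ± 0.09 (adjusted p = 0.0483), a call lost without any of the 6 untreated libraries (adjusted p = 0.0894 to 0.127), replicate 2 of treated wild type (0.0613) or replicate 3 of the treated edited line (0.0584). It was also lost with no filter (0.0733), quantile normalization (0.0660), TMM factors (0.0536) or the GC trend removed (0.0557). ZEB1 (-0.22 ± 0.10, adjusted p = 0.129) passed without replicate 1 or 3 of treated wild type (adjusted p = 0.0247 and 0.0469) or replicate 1 of both treated groups (0.0204), with the length trend removed (0.0139) or only the compared groups in the fit (0.0206). SNAI2 (-0.19 ± 0.37) did not pass and was at 0.24 without replicate 2 of untreated wild type.

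Of 20 p53 targets, 16 were higher and 0 lower in the untreated edited line, led by the cell cycle inhibitor CDKN1A (1.28 ± 0.07) and ZMAT3 (1.03 ± 0.08) (camera adjusted p = 4.49e-09; adjusted p = 0.0814 with an estimated correlation). Proliferation genes were lower in 16 of 30 members and higher in 0, including the cell cycle transcription factor E2F1 (-1.42 ± 0.09), the nucleotide synthesis gene RRM2 (-1.31 ± 0.07) and the replication helicase subunit MCM3 (-1.27 ± 0.07) (camera adjusted p = 3.50e-08; adjusted p = 0.279 with an estimated correlation). Cytokine and NF-kB genes were lower in 15 of 25, with CCL2 at -1.77 ± 0.10, and higher in 2, IL11 (1.96 ± 0.06) and IL1B (1.68 ± 0.46) (camera adjusted p = 4.27e-06; adjusted p = 0.157 with an estimated correlation). The IL1B call was lost without replicate 1 of untreated wild type (1.20) or replicate 3 of the untreated edited line (1.32), or with only the compared groups in the fit (adjusted p = 0.0577). Adjusted over the list alone, 17 cytokine genes were lower and 3 higher, 13 cholesterol genes were lower, and the other called lists of this comparison had equal counts. Without replicate 1 of untreated wild type the median of the cytokine list was -0.35 in place of -0.53.

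Fatty acid synthesis genes were lower in 9 of 12 members, with the desaturases FADS2 (-1.14 ± 0.08) and SCD (-0.82 ± 0.07), and cholesterol synthesis genes in 12 of 23. The camera adjusted p was 2.21e-05 for fatty acid and 0.000416 for cholesterol genes (adjusted p = 0.157 and 0.644 with an estimated correlation). The median of cholesterol genes was -0.29, and -0.19 without replicate 1 of untreated wild type. Hypoxia and glycolysis genes were lower in 12 of 25 and higher in 2, with ADM at -0.93 ± 0.08 (camera adjusted p = 0.00190; adjusted p = 0.610 with an estimated correlation). Epithelial genes were higher in 12 of 31 and lower in 4, with CLDN7 (1.30 ± 0.23) and the splicing regulator ESRP1 (1.30 ± 0.19) among the higher (camera adjusted p = 0.0352; adjusted p = 0.490 with an estimated correlation), a call also lost with the replicate number as a block (adjusted p = 0.0501). Ribosomal protein genes were higher in 8 of 25, with RPS6 at 0.45 ± 0.10. Histone genes were higher in 5 of 11 and lower in 1. The camera adjusted p was 0.000321 for ribosomal and 0.0232 for histone genes (adjusted p = 0.686 and 0.490 with an estimated correlation). The histone call ended with the transcript length trend removed (adjusted p = 0.0526). NRF2 targets were lower in 11 of 25 and higher in 3 (camera adjusted p = 0.0283, and adjusted p = 0.681 with an estimated correlation). That call was lost without replicate 1 of untreated wild type or replicate 2 of the untreated edited line (list medians -0.14 and -0.15) or with a filter of 50 (adjusted p = 0.0663). Genes published as repressed by SNAI1 were not called, with 5 higher and 4 lower of 15 (camera adjusted p = 0.707). In total, 2927 genes were higher and 3587 lower in the untreated edited line, of which 612 and 412 changed at least 2-fold.

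The third comparison asked how the edited line responded to TGFβ. SPOCK1 (9.97 ± 0.24), COL5A1 (9.92 ± 0.14) and R3HDML (10.47 ± 0.45) rose, COL5A1 from 54.2 ± 10.4 to 52819 ± 2834. The mucin MUC5B fell from 33828 ± 3066 to 103 ± 11, and MUC5AC (-6.96 ± 0.28) and AHSG (-6.83 ± 0.53) also fell. CDH1 fell (-1.73 ± 0.06), and VIM (2.16 ± 0.09), FN1 (2.64 ± 0.14), CDH2 (3.94 ± 0.26), SNAI2 (4.55 ± 0.37) and ZEB1 (0.78 ± 0.10) rose. EPCAM was lower (-0.25 ± 0.09), a call lost without replicate 1 of the untreated edited line (-0.24) or replicate 2 of the treated edited line (-0.16), and with the length trend removed (-0.08).

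Mesenchymal genes rose in 22 of 24 members and fell in 0 in the edited line. Matrix proteases and inhibitors rose in 14 of 18, with ADAM19 at 7.35 ± 0.07, collagens in 16 of 22, with the crosslinking enzyme LOX at 5.08 ± 0.16, SMAD response genes in 20 of 24, with ANGPTL4 at 5.08 ± 0.11, and EMT transcription factors in 12 of 15, with SOX4 at 2.52 ± 0.06. These lists passed camera (adjusted p = 1.12e-11, 1.07e-05, 1.31e-09, 1.31e-09 and 0.00215), also with an estimated correlation (adjusted p = 0.00131, 0.00941, 0.00402, 0.0199 and 0.0368). NRF2 targets fell in 22 of 25, with OSGIN1 at -2.48 ± 0.08, ER stress genes in 16 of 21, with ASNS at -2.70 ± 0.09, and epithelial genes in 18 of 31, while 3, 2 and 5 members of these lists rose (camera adjusted p = 2.19e-06, 1.11e-06 and 0.0131; adjusted p = 0.273, 0.250 and 0.273 with an estimated correlation). Fibroblast markers rose in 5 of 6 (camera adjusted p = 0.0466; adjusted p = 0.184 with an estimated correlation), a call lost without replicate 1 or 3 of treated wild type or replicate 1 or 2 of the treated edited line (list medians 2.86, 2.86, 2.84 and 2.90), and with a pseudocount of 0.5 (adjusted p = 0.0522) or the length trend removed (0.0621). The summed count of fibroblast markers was 193 to 286 in untreated and 1785 to 2118 in treated libraries of the edited line. Counts of these called lists adjusted over the list alone were equal. In total, 6559 genes were higher and 6283 lower, of which 3194 and 2195 changed at least 2-fold.

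The TGFβ responses of the lines were compared over the 20456 genes, which are not independent replicates. Their log2 fold changes, which share no library, correlated at r = 0.889. Of the called genes, 5053 were higher in both lines and 4989 lower in both, against 2019 and 1943 for independent lists, and 76 and 142 went opposite ways.

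**Figure D3:**
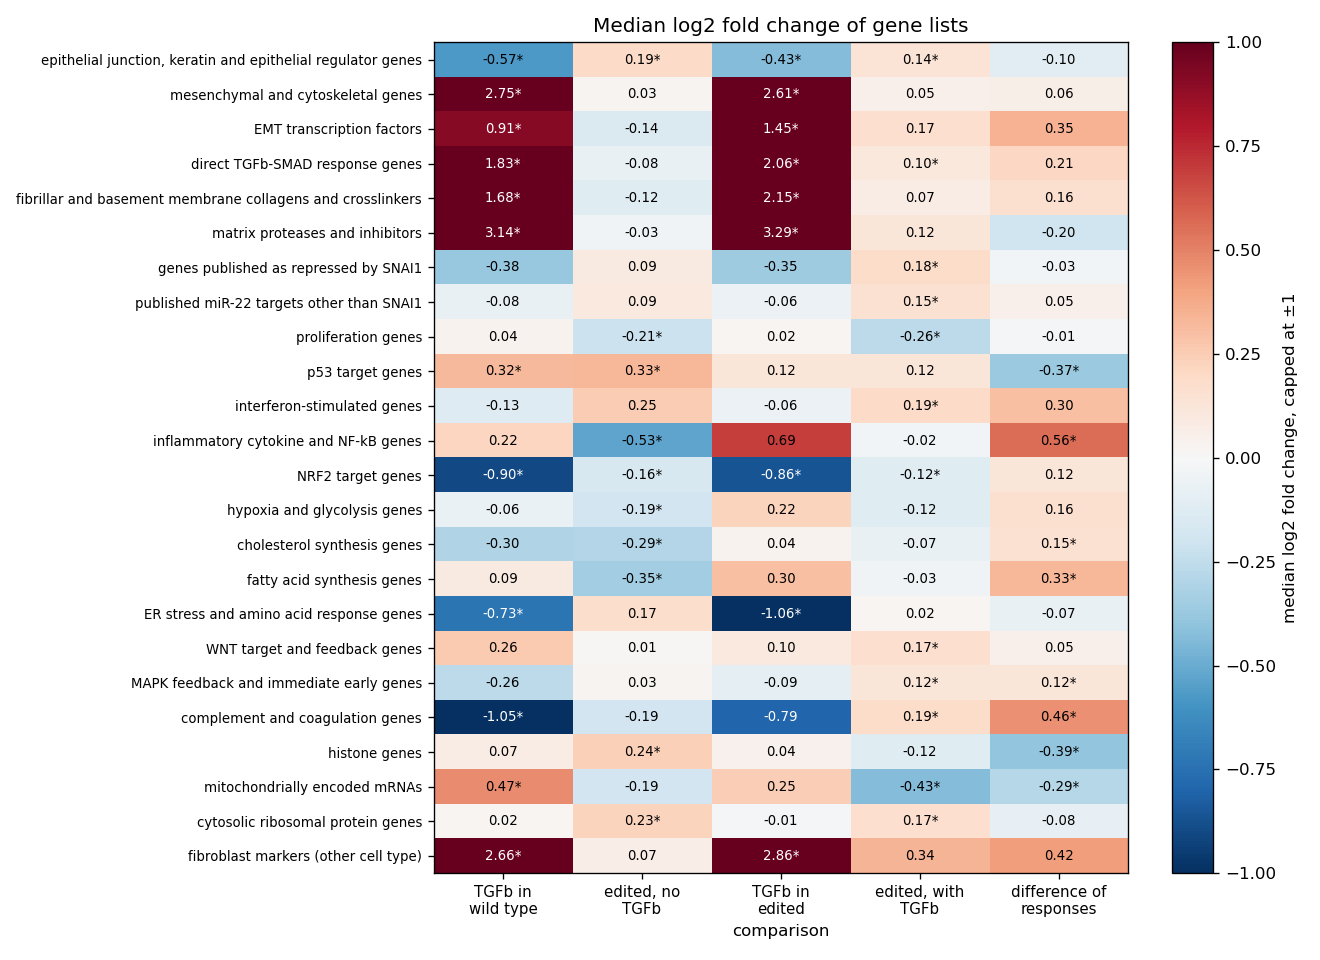
Median log2 fold change of gene lists called in at least 1 comparison (vertical axis) in the 5 comparisons (horizontal axis); colour is capped at ±1 and a star marks camera adjusted p under 0.05 at the preset correlation. Mesenchymal genes had medians of 2.75 and 2.61 with TGFβ in wild type and in the edited line, and of 0.03 and 0.05 between the lines without and with TGFβ.

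The fourth comparison asked how the lines differed with TGFβ. SLITRK6 averaged 1149 ± 131 in the edited line against 36.3 ± 4.58, CRISP3 232 ± 32.6 against 14.6 ± 7.08, and the adhesion receptor gene ADGRL3 484 ± 28.9 against 53.8 ± 8.44. OLR1 (-1.54 ± 0.21), ZNF229 (-1.35 ± 0.15) and PRSS35 (791 ± 19.1 against 1848 ± 89.5) were lower in the edited line. CDH2 was higher (1.19 ± 0.26, adjusted p = 0.00694), a call lost without replicate 1 of both treated groups (1.02, adjusted p = 0.0963). CDH1 (0.16 ± 0.06, adjusted p = 0.109), VIM (-0.04 ± 0.09, adjusted p = 0.850) and SNAI2 (0.81 ± 0.37, adjusted p = 0.175) did not pass, though SNAI2 did with a pseudocount of 10 (adjusted p = 0.0349) or DESeq2 (0.0150). VIM was above 0 without replicate 1 of treated wild type (0.0685). FN1 (0.36 ± 0.14) and ZEB1 (0.17 ± 0.10) did not pass, but did without replicate 3 of treated wild type (0.53 and 0.29). EPCAM was higher (0.36 ± 0.09), a call lost without replicate 2 of treated wild type (0.33) or replicate 1 (0.31) or 3 (0.33) of the treated edited line, or with only the compared groups in the fit (adjusted p = 0.102).

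Proliferation genes were lower in 20 of 30 members (26 adjusted over the list alone) in the edited line with TGFβ, with CDC6 at -0.53 ± 0.07 (camera adjusted p = 3.92e-17; adjusted p = 0.163 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 10 of 13 (13 adjusted over the list alone), with MT-ATP8 at -0.56 ± 0.09 (camera adjusted p = 9.25e-10; adjusted p = 0.284 with an estimated correlation). Mitochondrial reads made up 3.79%, 3.22% and 2.73% of the treated wild type libraries, and 2.35% ± 0.250 (SD, n = 3) of the treated libraries of the edited line. Across 13470 genes, which are not independent, the deviation of a library from its group mean correlated with log2 transcript length at -0.480, -0.00473 and 0.484 in treated wild type and at -0.269, 0.196 and 0.0569 in the treated edited line.

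Complement and coagulation genes were higher in 9 of 20 members in the edited line with TGFβ (11 higher and 2 lower adjusted over the list alone), with C3 at 0.91 ± 0.07 and CFI at 1.07 ± 0.07 (camera adjusted p = 0.000445; adjusted p = 0.259 with an estimated correlation). MAPK feedback genes were higher in 4 of 18 (6 adjusted over the list alone), with the phosphatase gene DUSP5 at 0.81 ± 0.06 (camera adjusted p = 0.00145; adjusted p = 0.234 with an estimated correlation). WNT target genes were higher in 5 of 13, equal when adjusted over the list alone, with LEF1 at 1.88 ± 0.25 (camera adjusted p = 0.00934; adjusted p = 0.208 with an estimated correlation). The median of WNT targets was 0.17, and 0.10 without replicate 3 of treated wild type and 0.28 without replicate 2 of the treated edited line. Published miR-22 targets other than SNAI1 were higher in 5 of 21 (8 higher and 2 lower adjusted over the list alone), with ERBB3 at 0.84 ± 0.07 (camera adjusted p = 0.0136; adjusted p = 0.163 with an estimated correlation). The median of these targets was 0.15, and 0.10 without replicate 1 of treated wild type.

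In the edited line with TGFβ, epithelial genes were higher in 5 of 31, SNAI1-repressed genes in 3 of 15 and ribosomal protein genes in 1 of 25, with equal counts adjusted over the list alone (camera adjusted p = 0.0212, 0.0366 and 0.00206; adjusted p = 0.290, 0.208 and 0.688 with an estimated correlation). These calls were lost without replicate 3 of treated wild type (list medians 0.09, 0.17 and 0.05) or replicate 1 of the treated edited line (0.09, 0.18 and 0.12), and that of SNAI1-repressed genes also without replicate 1 of treated wild type (0.14), with a pseudocount of 10 (adjusted p = 0.0632), a filter of 50 (0.0751) or the length trend removed (0.110). The median of ribosomal protein genes was 0.17, and 0.29 without replicate 1 of treated wild type. Interferon-stimulated genes were higher in 6 of 27 (10 higher and 1 lower adjusted over the list alone), with IFITM2 at 0.71 ± 0.11 (camera adjusted p = 0.0219; adjusted p = 0.163 with an estimated correlation), a call lost without replicate 3 of treated wild type (list median 0.28) or with a filter of 50 (adjusted p = 0.0751). NRF2 targets were lower in 4 of 25 and higher in 1 (7 lower and 3 higher adjusted over the list alone). Their camera adjusted p was 0.0268 (adjusted p = 0.607 with an estimated correlation). That call was lost without replicate 1 of treated wild type (-0.04) or replicate 2 of the treated edited line (-0.07). The median of NRF2 targets was -0.12, and -0.20 without replicate 3 of treated wild type. SMAD response genes were higher in 6 of 24 (6 higher and 2 lower adjusted over the list alone) (camera adjusted p = 0.0466; adjusted p = 0.436 with an estimated correlation), a call that 8 of the 12 libraries ended when left out (list medians 0.09 to 0.11, all but replicate 2 of untreated wild type, replicate 1 of treated wild type, replicate 3 of the untreated and replicate 2 of the treated edited line). It was also lost with a pseudocount of 10 (adjusted p = 0.0640), a filter of 50 (0.0824), equal totals (0.0697), quantile normalization (0.198) or the length trend removed (0.0501).

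In total, 1510 genes were higher and 884 lower in the edited line with TGFβ, of which 244 and 78 changed at least 2-fold. The share of higher genes was 63.1%, and 59.0% with TMM factors, 48.1% with equal totals and 50.4% with quantile normalization. The count of lower genes was 417 (41 at least 2-fold lower) without replicate 2 and 1580 without replicate 3 of treated wild type, and without replicate 3 of the treated edited line 491 were lower and 896 higher.

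The interaction asked whether the lines responded differently to TGFβ. The response was more positive in the edited line for VIM (0.53 ± 0.12) and EPCAM (0.60 ± 0.13), as for SNAI1 above. No difference was detected for CDH1 (adjusted p = 0.462), CDH2 (adjusted p = 0.856), FN1 (adjusted p = 0.651) or SNAI2 (adjusted p = 0.215). ZEB1 (0.39 ± 0.15, adjusted p = 0.0908) passed without replicate 3 of treated wild type (0.51), with the length trend removed (adjusted p = 0.0238) or with the replicate number as a block (0.0299). PAPPA2 (-2.80 ± 0.30), MMP2 (-2.33 ± 0.54) and DCLK1 (-2.19 ± 0.29), higher in the untreated edited line, had a negative interaction. MMP2 had few reads in untreated wild type, as given above, so the size of its interaction depends on the pseudocount. The interaction was positive for IGFL1 (2.55 ± 0.38) and the imprinted transcript H19 (2.20 ± 0.38).

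Cytokine and NF-kB genes had a positive interaction in 15 of 25 members (16 adjusted over the list alone), with the neutrophil chemokine CXCL8 at 1.66 ± 0.13 (camera adjusted p = 1.39e-06; adjusted p = 0.138 with an estimated correlation). So had complement genes in 10 of 20, fatty acid genes in 8 of 12, with FADS2 at 0.86 ± 0.12, and MAPK feedback genes in 7 of 18, with FOS at 1.23 ± 0.13 and JUN at 1.06 ± 0.09 (camera adjusted p = 3.06e-05, 3.06e-05 and 0.00832; adjusted p = 0.338, 0.138 and 0.373 with an estimated correlation). Adjusted over the list alone these counts were 13, 8 and 8. Cholesterol genes had a positive interaction in 7 of 23 (9 adjusted over the list alone; camera adjusted p = 0.0152; adjusted p = 0.679 with an estimated correlation), a call lost without replicate 1 of untreated wild type or replicate 3 of the treated edited line (list medians 0.07 and 0.12), or with a filter of 50 (adjusted p = 0.0574) or quantile normalization (0.0847). The p53 targets had a negative interaction in 13 of 20 members, equal when adjusted over the list alone, with CDKN1A at -1.06 ± 0.10 (camera adjusted p = 8.98e-08; adjusted p = 0.126 with an estimated correlation). Histone genes had it in 4 of 11 (5 adjusted over the list alone), with HIST1H2BC at -0.95 ± 0.18 (camera adjusted p = 0.00463; adjusted p = 0.373 with an estimated correlation). In total, 2163 genes had a positive and 1232 a negative interaction. The positive share of 63.7% was 57.6% with TMM factors, 51.5% with equal totals and 53.4% with quantile normalization.

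Whether the untreated edited line lay along the TGFβ direction was tested over all genes, which are not independent. Of 2339 genes at least 2-fold higher with TGFβ in both lines, 314 were higher and 430 lower in the untreated edited line, and of 1443 genes at least 2-fold lower, 358 were higher and 157 lower. A gene already shifted that way in the untreated edited line would change less with TGFβ there and could leave these sets. The correlation of its changes with the wild type TGFβ response was r = 0.101, where simulated unchanged groups gave 0.50 from the shared untreated wild type libraries. The simulated groups hold no TGFβ response, so these correlations are not on the same scale and the covariances are compared instead. The covariance was 0.0824 against 0.0585 in the simulation, a difference of 0.0238. Of the called genes, 1094 were higher in both and 1480 lower in both, against 901 and 1109 for independent lists. Genes called in opposite directions also exceeded independent lists, with 1187 higher with TGFβ and lower in the edited line against 1104, and 1044 the other way against 905. With the untreated wild type libraries split 1 against 2, so that the comparisons shared none, the 6 splits gave r = 0.0249 on average and covariances of -0.00348 to 0.0371 (mean 0.0222), a test chosen after the data were seen. The overlaps were not counted with split libraries, so part of the same-direction excesses may come from the shared ones. The shared libraries act against overlaps in opposite directions. Against the edited line's own TGFβ response, which shares libraries with the opposite sign, the covariance differed from the simulation by -0.141. The untreated edited libraries were also split in the same way, after the data were seen. The 6 splits gave r = -0.156 on average and covariances of -0.165 to -0.127 (mean -0.144), so the negative sign did not rest on shared libraries. A shift of the untreated edited line enters both comparisons with opposite signs, so this value does not decide the question.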

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

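The tests of explanations and of other splits in this part were chosen only after the results were seen, while the interaction test was planned. By the interaction test, 3395 genes responded differently to TGFβ in the lines. Among the named genes these included SNAI1 (0.62), VIM (0.53), EPCAM (0.60), ADH4 (2.91), LINC00284 (2.59), FOXS1 (2.57), IGFL1 (2.55), H19 (2.20), PAPPA2 (-2.80), COL22A1 (-2.65), MMP2 (-2.33), DCLK1 (-2.19) and SLC16A6 (-2.18), as log2 differences of the responses. The calls of LINC00284, FOXS1 and COL22A1 were lost in 9, 7 and 7 of the 12 fits without a library, which gave 2.53 to 2.68, 2.14 to 2.63 and -2.76 to -2.45. They held for LINC00284 without any treated wild type library (1.70 without replicate 3), for FOXS1 without replicate 1 of untreated wild type, replicate 1 or 3 of treated wild type, replicate 3 of the untreated or replicate 2 of the treated edited line, and for COL22A1 without any untreated wild type library (-1.53 without replicate 2) or replicate 1 or 3 of treated wild type. With no filter on low values all 3 calls were lost (adjusted p = 0.0552, 0.0677 and 0.0552), as under other alternatives. The size of the MMP2 value also rests on few reads in untreated wild type. The lists that differed were p53 targets (median -0.37), cytokine and NF-kB genes (0.56), cholesterol (0.15) and fatty acid synthesis (0.33), MAPK feedback (0.12), complement (0.46), histones (-0.39) and mitochondrially encoded mRNAs (-0.29). All 8 missed the threshold with the correlation of members estimated, in that order at adjusted p = 0.126, 0.138, 0.679, 0.138, 0.373, 0.338, 0.373 and 0.679 with an estimated correlation. The mitochondrial list had 0 members called, and its call was lost with the length trend removed (-0.12) and without replicate 1 of treated wild type (-0.16). The interaction does not tell a changed response from a different untreated state. At the preset correlation the p53, cytokine, cholesterol, fatty acid and histone lists were called between the untreated lines (medians 0.33, -0.53, -0.29, -0.35 and 0.24). With TGFβ they were not (0.12, -0.02, -0.07, -0.03 and -0.12). The complement, MAPK feedback and mitochondrial lists were called between the lines only with TGFβ.

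Regrouping the genotypes within each treatment in 100 of the 200 distinct splits gave as many interaction calls in 2, the real one included, with 3395 for the real split and 3587 for the highest other. That share is under 0.05, but this draw does not firmly exclude chance, because it replaced an earlier draw of 100 regroupings, which counted repeats and mirrored splits, after that draw had given as many in 5, the real one included, and the other 100 distinct splits were not run. Of the others as large in the earlier draw, 2 mixed the genotypes (highest 3765) and 2 kept each genotype whole within each treatment. Exchanging whole genotypes in 1 treatment (5997 genes) tests the summed difference between the lines, a structure of the samples, and was not used to judge chance. For the other comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many in each. The real split called 12624 genes for TGFβ in wild type, 6514 for the untreated edited line, 12842 for TGFβ in the edited line and 2394 for the edited line with TGFβ, and the highest other called 0, 0, 0 and 2. A split that mixes groups which differ moves that difference into the spread, which lowers its calls. These low counts, and those of the mixed interaction splits, therefore do not measure chance alone.

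SNAI1 was higher in the edited line with TGFβ, with no difference detected without it. Removing the transcript length trend left the log2 fold change at 0.624, and chromosome 20 genes had a median of -0.0161, which argue against length bias and extra copies of that chromosome as the whole cause. Loss of a miR-22 site in SNAI1 may raise SNAI1 where MIR22HG is higher, but the difference was -0.0308 without TGFβ, where MIR22HG was also expressed. Mature miR-22 was not analysed here and there is 1 edited derivative, so the edit and other changes in that line cannot be told apart.

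In the untreated edited line, proliferation, cytokine, fatty acid and cholesterol synthesis lists were lower and p53 targets higher, calls that were lost at adjusted p = 0.279, 0.157, 0.157, 0.644 and 0.0814 with an estimated correlation. Genes at least 2-fold higher with TGFβ in both lines had a median of -0.0164 there (314 higher, 430 lower), and those at least 2-fold lower 0.157 (358 higher, 157 lower). A gene already shifted there could leave these sets, so they cannot count against TGFβ-like signalling. Against it, TGFβ in wild type moved the proliferation (9 higher, 9 lower), cytokine (12 and 10) and fatty acid lists (5 and 5) both ways. However, it moved p53 targets (13 and 4, median 0.322) and cholesterol genes (5 and 15, median -0.302) as in the untreated edited line (camera adjusted p = 0.0370 and 0.0815). TGFβ-like signalling stays open, also because the covariance with the wild type TGFβ response, with separate control libraries, ran from -0.00348 to 0.0371. With the edited line's own response and separate libraries it ran from -0.165 to -0.127. That range cannot decide, because the untreated edited line enters both comparisons with opposite signs. SNAI1 mRNA was at -0.03, but SNAI1 protein was not analysed here, so this value does not decide on SNAI1 activity. Against more SNAI1 activity, CDH1 was at 0.26 ± 0.06, VIM at -0.57 ± 0.09 and the epithelial list had 12 higher and 4 lower of 31. Other markers went the opposite way, with CDH2 (at low counts) and FN1 higher and EPCAM lower, as given above. The published repressed genes moved both ways (median 0.0911), so more SNAI1 activity stays open. A different growth state or density of the cultures could also accompany the 16 higher p53 targets, and the labels give neither density nor passage. The edit itself stays open, since line and genotype coincide.

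Genes on chromosome 9 were higher in the edited line, with medians of 0.15 without and 0.19 with TGFβ over 525 genes. None of 10000 lists matched on length, GC content and expression reached the value with TGFβ (highest 0.0347), and the lower quartile lay 0.180 above that of other chromosomes, which argue against gene properties and a few strongly changed genes. Of 12 blocks of 10 Mb, 12 with and 11 without TGFβ lay above the other chromosomes, which is consistent with extra copies of chromosome 9 in the edited cells, a hypothesis that needs DNA data. Chromosome 8 had medians of 0.06 and 0.15, with 10 and 15 of 15 blocks above. The gene lists, such as ribosomal protein genes, were not tested without chromosomes 8 and 9. Whether these chromosomes account for list calls between the lines is therefore open.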

How the results depend on the processing

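The alternatives that removed length or GC trends or left out the 2 libraries most shifted toward short transcripts (replicate 1 of each treated group) or chromosomes 8 and 9, or split the untreated wild type libraries, were chosen only after the results were seen. Counts of calls not listed here stayed within 1.5 times their main value under every alternative run. For the untreated edited line, genes at least 2-fold higher numbered 398 with a pseudocount of 10 and 405 with a filter of 50 (main 612), and 237 were lower with the pseudocount of 10 (main 412). The pseudocount shrinks the fold changes of low genes by construction, and the filter leaves such genes out. For the edited line with TGFβ, the higher and lower counts were 859 and 324 with only the compared groups in the fit (fewer samples), and 1198 and 828 without chromosomes 8 and 9. The lower count was 1355 with equal totals, 1345 with quantile normalization and 540 without the 2 short-shifted libraries. At least 2-fold lower were 41 (pseudocount 10), 51 (filter 50) and 37 (compared groups only). Leaving out a library gave 896 to 2249 higher, 417 to 1580 lower and 41 to 89 at least 2-fold lower genes. The cause was not tested where none is given.

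Without the 2 short-shifted libraries, VIM with TGFβ (0.0504) and the CDH2 interaction (-0.0415) changed sign, neither being called, and CDH2 with TGFβ lost its call (1.02). Leaving out a library gave log2 ranges of -0.18 to 0.0853 for SNAI1 and -0.42 to 0.24 for SNAI2 in the untreated edited line, and -0.16 to 0.0685 for VIM with TGFβ. For the interaction they were 0.50 to 0.76 (SNAI1), -0.36 to -0.20 (MIR22HG), -0.0938 to 0.31 (CDH2) and -0.33 to 0.0066 (FN1). The correlation of the TGFβ responses was 0.827 by rank, 0.915 with a pseudocount of 10, 0.766 with no filter, 0.938 with a filter of 50, and 0.875 to 0.886 without a library. The correlation of the edited line with the TGFβ direction was 0.177 with no filter and 0.0249 with the control libraries split. Of 51 list calls, 42 were lost with an estimated correlation, 5 with the length trend removed, 5 with a filter of 50 and 2 with quantile normalization. Reads limit the low genes first, and calls on genes with few reads rest on the pseudocount and filter. With the replicate number as a block, the edited line with TGFβ had 1863 higher and 1124 lower genes, the untreated epithelial list missed the threshold, the ZEB1 interaction passed (0.39), and no other call reported here changed. The 18 pairs with the same number had correlations of -0.0310 to 0.129 (median 0.0110), 2 over 0.1, and 8 of 12 libraries correlated best with their own number. The main fit did not pair the samples by number, but these values do not exclude a batch shared by number.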

Other observations

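The comparison of the edited line's differences without and with TGFβ was chosen only after the results were seen; the gene lists were planned. Over the 20456 genes, log2 fold changes between the lines without and with TGFβ, which share no library, correlated at r = 0.279. Of the called genes, 669 were higher in the edited line in both conditions and 443 lower in both, against 216 and 155 for independent lists, and 66 and 168 went opposite ways. The matrix glycoprotein TNC was higher without (2.54 ± 0.24) and with TGFβ (1.88 ± 0.24), as were the plasminogen activator PLAU (1.62 ± 0.06 and 1.07 ± 0.06) and the metalloprotease ADAM12 (1.69 ± 0.23 and 1.74 ± 0.23). COL1A1 was lower in both (-0.79 ± 0.09 and -0.53 ± 0.09), and the actin-binding gene CNN1 was lower with TGFβ (-2.00 ± 0.34).

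As lists, these groups were not called between the untreated lines. Of 18 matrix proteases and inhibitors 7 were higher and 3 lower (camera adjusted p = 0.132), of 22 collagens 4 and 6 (adjusted p = 0.969), and of 24 mesenchymal genes 8 and 6 (adjusted p = 0.486). YAP-TEAD targets had 6 higher and 11 lower of 20 (adjusted p = 0.119). With TGFβ in wild type, antigen presentation genes had 8 higher and 4 lower of 15 (adjusted p = 0.582), alveolar lineage genes 4 and 2 of 10 (adjusted p = 0.497), and proliferation genes 9 and 9 of 30 (adjusted p = 0.918). BMP and inhibin genes had 7 and 6 of 15 (adjusted p = 0.918), stemness-associated genes 4 and 4 of 11 (adjusted p = 0.918) and cytostatic inhibitors 4 and 2 of 9 (adjusted p = 0.700). Metallothioneins, with 4 tested members, were too few to test as a list; 2 were higher in wild type with TGFβ.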
